A study of Saccharomyces cerevisiae with 27 samples.

How the data were processed

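RNA was measured by paired-end sequencing of poly-A selected RNA from 27 libraries of Saccharomyces cerevisiae, in 9 groups of 3, which the submitters describe as biological replicates. Groups were taken from the sample titles. The values analysed are those of the authors' deposited table, which holds 1 value per gene and comparison for 5 pairwise comparisons and no column per library, so 0 columns of per-sample values were left aside.

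Per the file headers, the first block of columns in the authors' deposited table is log2 differential expression, read here as the log2 of the first named group over the second. The second block is the authors' q value, a p value adjusted for false discovery rate. Per the submitters' processing notes, the tools were Trimmomatic 0.33, TopHat2 2.0.14 and Cuffdiff 2.2.1, and the genome build was R64. Their settings, the annotation and the use of strand are not given in the sources used here. The reading of the direction rests on the column names and on the target genes of both fragment comparisons, which were higher where the labels say that the fragment was expressed.

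The authors' deposited table gives 6709 genes here, after 4 emptied lines were left out. A value of exactly 10 or -10 was taken, from the values and not from a header, to stand for a ratio with no finite log2, where 1 of the groups was listed at 0. An exact 0 always came with a q of 1 and was taken as no value given. Genes with a q under 1 were taken as tested. One gene symbol had been turned into a date by a spreadsheet and is shown by its systematic name. By systematic name, 6022 genes matched the RefSeq annotation of R64, and 5378 of them had the same end and a start 1 base lower, as a 0-based start would be. Positions below are the 1-based RefSeq ones. Older symbols were matched through RefSeq, so that FEN1, SUR4, MVD1, MUC1 and YLR194C were counted as ELO2, ELO3, ERG19, FLO11 and NCW2.

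No counts, expression levels, standard errors, unadjusted p values or values per library were used here, so the depth is unknown. No test of a group difference was run in this work, and no SD or n stands beside a value. A gene is said to have risen or fallen where the authors' q was under 0.05. The lowest q, 0.000304, was the same in all 5 comparisons and was shared by between 43 and 1136 genes, so q does not rank the strongest genes. That shared value would follow from 1 adjustment over all comparisons together, but the procedure is not given in the sources used here.

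For 24 gene lists fixed before the data were examined, the members that rose, fell or did not pass were counted among those tested. These lists were fatty acid synthesis, ergosterol synthesis, phospholipid and inositol synthesis, hypoxic Rox1 targets, anaerobic cell wall and sterol uptake genes, seripauperins, flocculation and adhesion, respiratory chain, TCA cycle, glycolysis and fermentation, methionine and sulfur, heat shock and stress, unfolded protein response, ribosomal proteins, ribosome biogenesis, iron regulon, Gcn4-type amino acid synthesis, cell wall integrity, beta-oxidation and peroxisome, glucose-repressed genes, phosphate regulon, a-specific mating genes, alpha-specific mating genes, and strain markers. The median log2 fold change of each list with at least 3 tested members was placed among 10000 random lists of the same size, drawn from the tested genes of that comparison. The planned matching on mean expression needs expression levels and could not be applied. Unmatched lists were drawn instead, which departs from the plan. The percentile is a description of these values and not a test, because members of a list share regulation. Of 115 such medians, 49 lay above percentile 97.5 and 18 below percentile 2.5. A count adjusted over the list alone needs unadjusted p values and was not made.

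The named genes are OLE1, SPT23 and MGA2, the 10 largest rises and 10 largest falls among genes past the threshold, and up to 3 members of each list past the threshold with the largest absolute change. The planned minimum on expression level could not be applied, so only values listed at 10 or -10 were excluded from this choice, and some of the named genes can be weakly expressed. The text names part of this set. Genes past the threshold in 2 comparisons were counted by direction beside the number that independent lists would share, n1 x n2 / N, over the N genes tested in both. Pearson and Spearman correlations were taken across genes with finite values, and genes are not independent replicates. Differences between 2 log2 fold changes are values without a test.

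The step for the gene lists was tested on simulated log2 values of 6000 genes with an SD of 0.9. Of 400 lists of 20 genes without a shift, 5.8% fell outside the percentiles 2.5 and 97.5. Of lists shifted by 0.3, 0.6 and 1, 19.8%, 71% and 98.8% did. The simulated genes were independent and had 1 spread, while list members share regulation and the spread differed between comparisons. The interquartile range of tested genes was -0.189 to 0.276 in ArgonST and -0.494 to 0.728 in ArgonLT. These rates therefore check the step and do not apply to the lists themselves. Alternatives planned before the data were examined were a q under 0.01 and a minimum change of 2-fold. Those added after seeing the data were leaving out values of 10 or -10, keeping only genes matched to RefSeq, including genes at a q of 1 in the list medians, and centring on the median of the tested genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.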

Results

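Transcript levels were compared in budding yeast whose membrane lipids or oxygen supply had been altered. In a strain carrying the OLE1 gene under the MET3 promoter, which methionine represses, the groups OLE1met0 and OLE1met250 are described as high and low in lipid unsaturation. OLE1 encodes the acyl-CoA desaturase that makes unsaturated fatty acids. In 2 further strains, a plasmid carried the processed p90 fragment of SPT23 or of MGA2, homologous membrane-anchored activators of OLE1, and each fragment was expressed without doxycycline and repressed with it. The background strain BY4742 was grown aerobically (BY), under argon for 90 min (ArgonST) or in a microfermenter described as long-term hypoxia (ArgonLT). Each of the 9 groups had 3 libraries, and the 5 comparisons of the design follow in turn. Every log2 fold change and q value comes from the authors' deposited table, which carries no error and no value per library, so the spread between replicates enters only through the authors' q and the depth is unknown.

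The number of genes called at a q under 0.05 in the authors' deposited table ranged from 398 of 5474 tested genes in ArgonST to 2424 of 5702 in ArgonLT. The other comparisons had 1893 of 6065 genes for OLE1met250, 1165 of 5606 for the MGA2 fragment and 695 of 5626 for the SPT23 fragment. Genes listed at 10 or -10, that is at 0 in 1 of the 2 groups, are left out of the largest rises and falls named below. The smallest called absolute log2 fold change lay between 0.51 and 0.52 in all 5. The median log2 fold change of tested genes was between -0.04 and 0.05 in 4 comparisons and 0.10 in ArgonLT. No list median past the percentile limits changed sign when that median was subtracted. No call could change sign, as every called value was larger than the median subtracted. LEU2 and LYS2, deleted in BY4742, were listed at 0 with a q of 1 in all 5 comparisons.

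**Figure D1:**
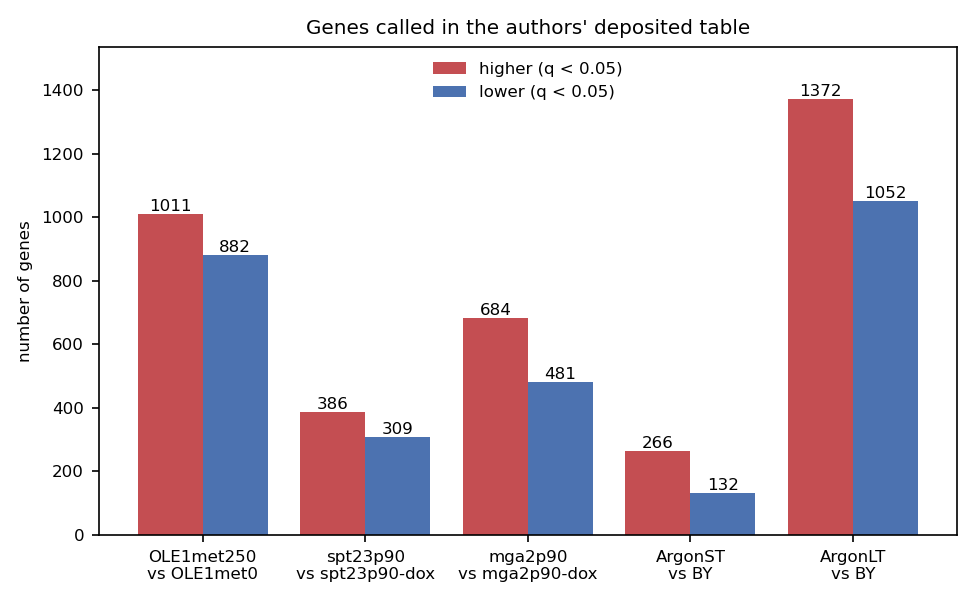
Number of genes (vertical axis) with a higher or lower level at a q under 0.05 in each of the 5 comparisons of the authors' deposited table (horizontal axis). ArgonLT had the most calls, 1372 higher and 1052 lower, and ArgonST the fewest, 266 higher and 132 lower.

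The first comparison sets OLE1met250 against OLE1met0, where OLE1 was to be repressed through its MET3 promoter. By this design methionine and the intended repression of OLE1 change together, so their effects cannot be told apart. Per the authors' deposited table, OLE1 itself (YGL055W, chromosome VII, 398628 to 400160, 1 exon) had a log2 fold change of -0.03 at a q of 0.925, so the target does not check the direction of the labels, and the groups are called here by their titles. The treatment label of the group titled OLE1met250 reads 0 uM methionine (repressed), while its title carries the number 250 and the file headers name it as the strain with methionine. In the group labelled OLE1met250, 1011 genes rose and 882 fell. Genes of fatty acid synthesis rose, with 9 of 13 members past the threshold and none called lower. FAA4, a fatty acyl-CoA synthetase, rose by 4.20 on the log2 scale, ACC1, the acetyl-CoA carboxylase, by 3.96, and both subunits of fatty acid synthase, FAS2 and FAS1, by 3.61 and 3.47. Genes of amino acid synthesis fell, with 31 of 32 members past the threshold, among them LEU1 at -2.88, TRP4 at -2.80 and ARG4 at -2.73.

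MGA2 (YIR033W, chromosome IX, 416124 to 419465, 1 exon) was 20.2-fold higher in the group labelled OLE1met250 in the authors' deposited table (log2 4.33, q 0.000304), and SPT23 (YKL020C, chromosome XI, 398832 to 402080, 1 exon) had a log2 of 0.38 at a q of 0.175. The largest rise was that of IZH4, at 7.23 with a q of 0.0388. Beside MGA2 and FAA4, it was followed by HES1, of the oxysterol-binding protein family, at 5.38, FLO1 at 4.98, COS10 at 4.66, YLR413W at 4.62, RGI2 at 4.37, ADY2 at 4.14 and SPG1 at 4.13. FLO1 (YAR050W, chromosome I, 203403 to 208016, 1 exon) encodes a cell wall lectin that binds cells together in flocculation. The largest falls were those of STE2, the alpha-factor receptor, at -4.19, THI73 at -4.10, KAR4 at -3.99, AGA1 at -3.77, SRL4 at -3.72, YGL117W at -3.69, THI4 at -3.48, THI2 at -3.46, YHI9 at -3.42 and YOL118C at -3.29.

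Several cell surface and stress groups also rose in the group labelled OLE1met250. According to the authors' deposited table, 16 of 21 cell wall integrity genes rose and none fell (median log2 1.17, percentile 100), with NCW2 at 3.30, PST1 at 3.29 and PIR3 at 3.09. Of the genes of the unfolded protein response, 12 of 16 rose and none fell (median 0.89, percentile 100), with ULI1 at 2.11, PDI1, the protein disulfide isomerase, at 1.73 and HRD1 at 1.69. Anaerobic cell wall and sterol uptake genes rose in 8 of 10 members, with TIR4 at 3.62 and DAN1 at 3.27. The hypoxic Rox1 targets had few calls, with 1 rise (HMG2, 1.31) and 1 fall (COX5B, -1.03) among 8. Even so, 7 of the 8 values were positive, and the list median of 0.57 lay at percentile 97.2, inside the percentile limits. The flocculation and adhesion list split, with 5 higher and 4 lower of 12 tested: FLO9 rose by 0.92 and MGA1 by 2.26, while AGA1 and FIG2, both mating agglutination genes, fell with values of -3.77 and -2.42. Of the heat shock and stress genes, 7 of 24 rose and none fell, led by SSA3 at 3.55 and HSP26 at 2.27. The iron regulon had 13 of 20 members higher, with SIT1 at 2.60 and TIS11 at 2.38.

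Carbon metabolism shifted as well. In the authors' deposited table, 17 of 28 genes of glycolysis and fermentation rose and 4 fell (median 1.38, percentile 100), with GPM1 at 2.99, ENO1 at 2.96 and TDH1 at 2.81 in the group labelled OLE1met250. Glucose-repressed genes rose in 14 and fell in 5 of 21 members. PCK1 of gluconeogenesis was at 3.97 and SFC1 at 3.89, and the hexose transporter HXT4 was at -2.98. Of the genes of beta-oxidation 7 of 16 rose and 1 fell, with SPS19 at 2.69. The respiratory chain had 1 rise and 5 falls among 32 genes, and the TCA cycle 1 rise and 2 falls among 17. Phospholipid and inositol synthesis rose in 9 and fell in 2 of 17, with INO1, the inositol phosphate synthase, at 3.14 and CHO2 at 1.61. Ergosterol synthesis had 6 rises, such as ERG19 at 1.75, and 6 falls among 26.

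Methionine and sulfur genes fell in 14 and rose in 1 of 29 members in the group labelled OLE1met250 (median -0.65, percentile 0.01), with MET16 at -3.10, SUL1 at -2.00 and MET5 at -1.88. MET3 itself had a log2 of 0.36 at a q of 0.274 in the authors' deposited table. Ribosomal protein genes fell in 39 and rose in 2 of 136 (median -0.40), and ribosome biogenesis genes fell in 12 of 37 with none called higher. All 4 alpha-specific mating genes fell, such as MF(ALPHA)2 at -2.49, and so did 4 of the 7 a-specific genes, such as ASG7 at -2.82. The phosphate regulon had 1 rise and 1 fall among 14, the seripauperins 1 rise (PAU5, 2.59) among 5, and the strain markers 1 rise (MGA2) and 1 fall (MET17, -1.48) among 5. With a minimum change of 2-fold, 937 of the 1893 genes were counted. FLO1 and FLO9, the TDH genes, the hexose transporters and paired ribosomal protein genes share near-identical sequence, so their reads can be split between copies and their values are uncertain in every comparison.

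**Figure D2:**
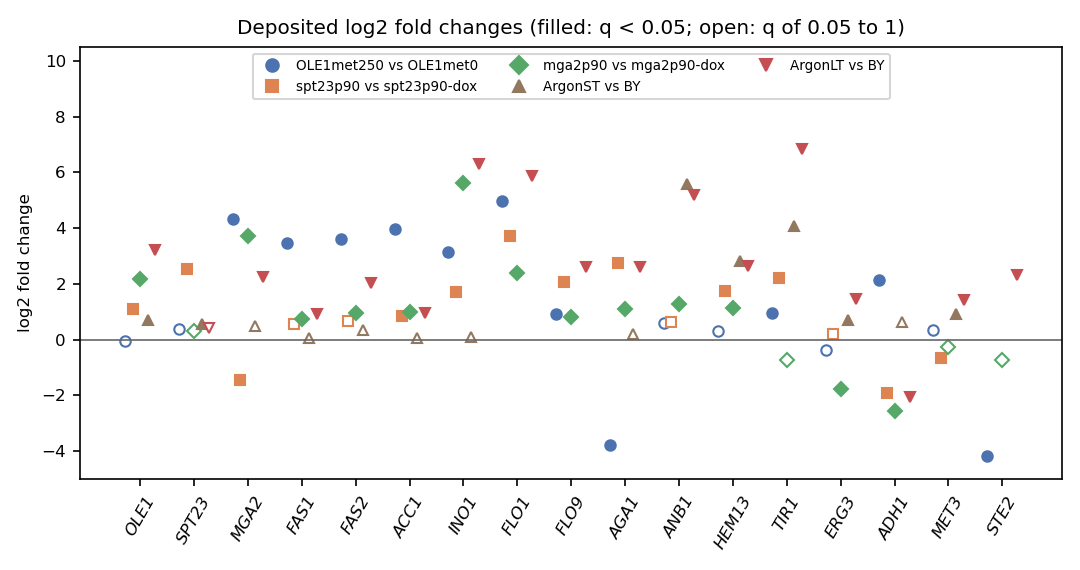
Deposited log2 fold changes (vertical axis) of 17 genes (horizontal axis) in the 5 comparisons, 1 symbol per comparison, filled where the authors' q was under 0.05 and open where it was 0.05 or more. Genes with a q of 1 in a comparison have no symbol there. OLE1 was near 0 in OLE1met250 and highest in ArgonLT at 3.20, while FLO1 was called in all comparisons except ArgonST, where it counts as not tested.

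The second comparison asks what the processed SPT23 fragment changes when it is expressed. Per the authors' deposited table SPT23 was 5.86-fold higher with the fragment expressed (log2 2.55, q 0.000304), as labelled, and OLE1 was 2.15-fold higher (log2 1.11, q 0.00259), while MGA2 fell by 1.46 on the log2 scale. In all, 386 genes rose and 309 fell. Of the iron regulon 12 of 20 genes rose, of the respiratory chain 12 of 31, and of the methionine and sulfur list 16 of 28 fell. FLO1 rose by 3.72 and FLO9 by 2.07. The fragment was repressed by doxycycline, so expression of the fragment and absence of the drug cannot be separated in this design.

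Beside FLO1, the largest rises with the SPT23 fragment in the authors' deposited table were those of GPG1 at 4.07, YOR387C at 3.58, the small heat shock gene HSP26 at 3.29, YDR124W at 3.00, YLR410W-B at 2.89, PEX27 at 2.77, AGA1 at 2.73, YBR012C at 2.70 and YNR073C at 2.69. The largest falls were those of SER3 at -2.47, ECM19 at -2.37, YLR349W at -2.36, DIC1 at -2.33, STR3 at -2.14, MUP3 at -2.03, YDR089W at -2.01, the alcohol dehydrogenase ADH1 at -1.93, and MMP1 and DIN7, both at -1.87. STR3, MUP3 and MMP1 belong to the methionine and sulfur list, in which 16 of 28 tested members fell and 1 rose (median -0.66, percentile 0).

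Of the iron regulon, 12 of 20 genes rose and none fell with the SPT23 fragment (median 0.74, percentile 100), with FIT1 at 1.62, FRE2 at 1.54 and TIS11 at 1.49. According to the authors' deposited table, 12 of 31 respiratory chain genes rose and none fell (median 0.44, percentile 100), with the ATP synthase genes ATP17 and ATP15 at 1.26 and 1.11. The flocculation and adhesion list had 6 rises and no fall among 13, among them FIG2 at 2.37. Glucose-repressed genes rose in 6 of 18, led by HXT6 at 2.67 and FBP1 at 2.25, and genes of beta-oxidation in 7 of 14, led by TES1 at 2.07. Cell wall integrity genes rose in 6 of 21, led by PIR3 at 1.50.

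In the authors' deposited table, 2 of 13 fatty acid synthesis genes rose with the SPT23 fragment, OLE1 and ACC1 (0.84), and the list median of 0.39 lay at percentile 99.3. Phospholipid and inositol synthesis had 3 rises and 1 fall among 17, with INO1 at 1.72 and OPI3 at 0.92. Ergosterol synthesis had 1 rise among 26, ERG5 at 0.52. Of the hypoxic Rox1 targets HEM13 rose by 1.73, 1 of 8, and of the anaerobic cell wall genes TIR1 rose by 2.20 and DAN4 by 1.03, among 9. Seripauperins had 2 rises and 1 fall among 6, all listed at 10 or -10.

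Glycolysis and fermentation had 6 rises and 3 falls among 27 with the SPT23 fragment in the authors' deposited table, the TCA cycle 4 and 4 among 17, and heat shock and stress 3 and 3 among 24. No gene of the unfolded protein response was called among 15. Ribosomal protein genes had 2 falls among 135, though 117 were below 0 and the median of -0.24 was at percentile 0. Ribosome biogenesis had 1 rise and 1 fall among 37, amino acid synthesis 1 rise and 4 falls among 32, and the phosphate regulon 1 rise among 10. Of the a-specific genes BAR1 rose by 1.33, 1 of 2 tested, and 2 of 4 alpha-specific genes rose, SAG1 at 1.40 and MF(ALPHA)2 at 0.77. The strain markers, a list that holds OLE1, SPT23 and MGA2, had 2 rises and 3 falls among 6. The rises were those of the expressed SPT23 and of OLE1, and the falls those of MGA2, URA3 at -0.72 and MET17 at -1.33. At a q under 0.01 the calls numbered 342 in place of 695. The medians of flocculation, cell wall integrity and alpha-specific genes no longer lay past the percentile limits when genes at a q of 1 were included.

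The third comparison asks the same of the processed MGA2 fragment. With it, MGA2 was 13.3-fold higher in the authors' deposited table (log2 3.73, q 0.000304), as labelled, and OLE1 was 4.52-fold higher (log2 2.18, q 0.000304), while SPT23 had a log2 of 0.32 at a q of 0.251. In all, 684 genes rose and 481 fell. INO1 (YJL153C, chromosome X, 134332 to 135933, 1 exon) had the largest finite rise past the threshold, at 5.61, and other genes of phospholipid and of fatty acid synthesis rose too. Ribosomal protein genes fell in 72 of 136 members. Doxycycline was again present only in the reference group.

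BIO3 and BIO5 of biotin synthesis and uptake of its precursors rose by 5.25 and 4.75 with the MGA2 fragment, and the biotin transporter VHT1 by 3.77. Per the authors' deposited table the other largest rises were those of the hexose transporter HXT6 at 5.11, SPS100 at 4.24, AAD10 at 4.17, YGL039W at 3.81 and SEO1 at 3.71. HXT6 shares sequence with HXT7, which was at 0.39 (q 0.261), so the value of HXT6 is uncertain. The largest falls were those of SCM3 at -2.70, ADH1 at -2.57, YLR049C at -2.55, YOL014W at -2.32, the glutathione peroxidase GPX2 at -2.24, QCR10 at -2.07, YNR014W at -2.06, the mannoprotein gene CWP1 at -1.98, YLR042C at -1.92 and YLR349W at -1.78.

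Of the phospholipid and inositol genes, 10 of 17 rose and none fell (median 0.92, percentile 100), with OPI3 at 1.77 and CKI1, choline kinase, at 1.54. According to the authors' deposited table, 8 of 13 fatty acid synthesis genes rose and none fell (median 0.88, percentile 99.99), with ACB1 at 1.75 and FAA4 at 1.39. Ergosterol synthesis went both ways with the MGA2 fragment, with 6 rises, such as ERG19 at 2.10 and ERG10 at 1.67, and 8 falls, such as ERG3 at -1.78, among 26. The unfolded protein response had 8 rises and no fall among 16, with KAR2, the ER chaperone BiP, at 1.11 and SIL1 at 0.97. Hypoxic Rox1 targets rose in 3 of 7, ANB1 at 1.29, HEM13 at 1.14 and HMG2 at 1.04, and anaerobic cell wall genes in 5 of 9, with DAN4 at 2.19 and TIR2 at 1.88. FLO1 rose by 2.40 and AGA1 by 1.11, and the flocculation and adhesion list had 5 rises and 2 falls among 13 (median 0.14, percentile 79.2).

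The iron regulon rose in 8 and fell in 1 of 18 genes with the MGA2 fragment, with TIS11 at 3.38 and ARN1 at 1.48. In the authors' deposited table ribosomal protein genes had a median of -0.67 at percentile 0, with 1 rise, RPL41B, which was listed at 10. Ribosome biogenesis genes fell in 5 of 37 (median -0.34, percentile 0.06). Methionine and sulfur genes had 4 rises and 6 falls among 28, with SAM2 at 1.74 and MET5 at -1.74. Heat shock and stress genes rose in 8 and fell in 1 of 24 (median 0.21, percentile 94.9), with the catalase CTT1 at 2.55. Glycolysis and fermentation had 6 rises, led by HXK1 at 2.56 and TDH1 at 2.47, and 5 falls among 28. Glucose-repressed genes rose in 5 and fell in 1 of 16, and beta-oxidation genes rose in 4 and fell in 1 of 11.

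The respiratory chain had 3 rises and 3 falls among 32 with the MGA2 fragment in the authors' deposited table, and the TCA cycle 1 and 3 among 17. Amino acid synthesis had 5 and 1 among 32, cell wall integrity 2 and 2 among 21, and the phosphate regulon 1 and 1 among 11. The fall in the phosphate regulon was that of PHM6, which was listed at -10. No seripauperin and no a-specific gene was called among 2 tested of each, and 1 of 4 alpha-specific genes rose, SAG1 at 0.99. Strain markers, a list that holds OLE1, SPT23 and MGA2, had 2 rises and 1 fall among 6. The rises were those of the expressed MGA2 and of OLE1, and the fall that of MET17. At a q under 0.01 the calls numbered 628 in place of 1165. The median of the Rox1 targets did not stay past percentile 97.5 when genes at a q of 1 were included.

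**Figure D3:**
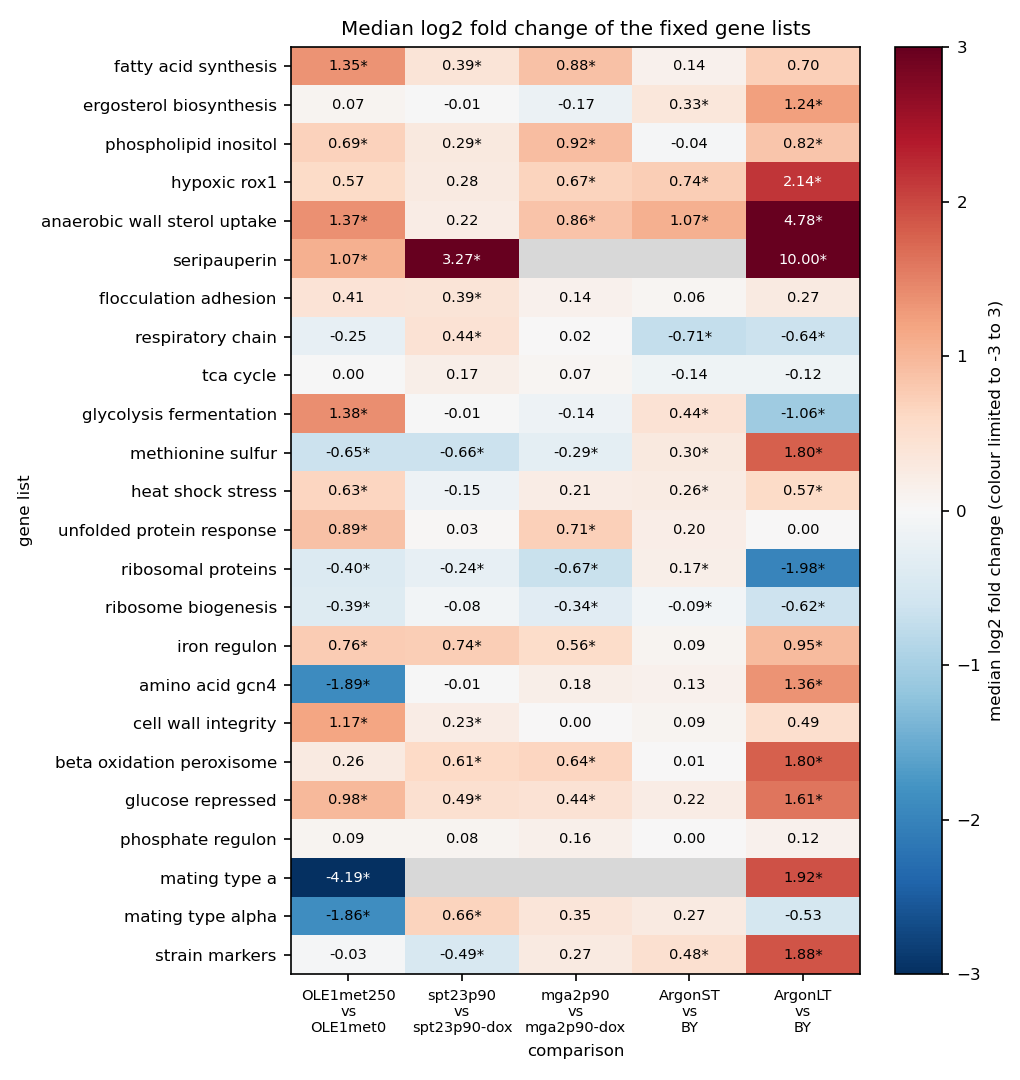
Median log2 fold change (colour and number) of the tested members of 24 fixed gene lists (vertical axis) in the 5 comparisons (horizontal axis). An asterisk marks a median outside the percentiles 2.5 and 97.5 of 10000 random lists of the same size, and grey marks lists with fewer than 3 tested genes. Ribosomal protein genes ranged from -1.98 in ArgonLT to 0.17 in ArgonST.

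The fourth comparison asks what 90 min under argon changes in the background strain. Per the authors' deposited table, 266 genes rose and 132 fell. Genes of the hypoxic programme rose, led by ANB1 (YJR047C, chromosome X, 524908 to 525381, 1 exon), an oxygen-repressed form of the translation factor eIF5A, which was 48.3-fold higher (log2 5.59, q 0.000304). Genes of the respiratory chain fell, with 17 of 31 past the threshold and none called higher. OLE1 was 1.64-fold higher (log2 0.72, q 0.0364) and SPT23 rose by 0.57, while MGA2 had a log2 of 0.48 at a q of 0.0769.

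The largest rises under short-term argon after ANB1 were those of the cell wall mannoprotein TIR1 at 4.06, HEM13 of haem synthesis at 2.84, YDR274C at 2.61, the ADP/ATP carrier AAC3 at 2.52, YDL186W at 2.20, the glycogen synthase GSY1 at 2.14, TOS8 at 2.02, SMD3 at 1.94 and PGM2 at 1.89. The largest falls in the authors' deposited table were those of GPX2 at -3.40, ATP19 at -2.02, QCR10 at -1.85, INH1 at -1.73, and the peroxiredoxins TSA1 and AHP1 at -1.72 and -1.67. LIN1, YPL191C, PEX15 and YLR036C followed between -1.68 and -1.45.

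Of the Rox1 targets, 4 of 7 rose and none fell under short-term argon (median 0.74, percentile 99.9), and of the anaerobic cell wall and sterol uptake genes 6 of 8 rose and none fell (median 1.07, percentile 100), with TIR2 at 1.35 and TIR3 at 1.16. According to the authors' deposited table ergosterol synthesis rose in 8 of 26 and fell in none (median 0.33, percentile 99.9), with ERG28 at 0.97, ERG25 at 0.95 and ERG11 at 0.89. The respiratory chain had a median of -0.71 at percentile 0, with RIP1 at -1.28. Fatty acid synthesis rose in 3 of 13, OLE1, FAA4 (1.05) and FAA1 (0.63). Glycolysis and fermentation rose in 5 of 27 and fell in none (median 0.44, percentile 100), with the hexokinase HXK1 at 1.14 and GPD2 at 0.88. Methionine and sulfur genes rose in 5 of 28 and fell in none, with MET14 at 1.19.

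Heat shock and stress genes had 6 rises and 3 falls among 24 under short-term argon in the authors' deposited table (median 0.26, percentile 99.3), with HSP12 at -1.12 and SOD1 at -1.05. Phospholipid and inositol synthesis had 1 rise among 17 (INO2, 1.04), the unfolded protein response 1 among 16 (EUG1, 0.95), amino acid synthesis 3 among 32, cell wall integrity 3 among 21, beta-oxidation 1 among 9, glucose-repressed genes 3 among 11 and the phosphate regulon 1 among 11. The TCA cycle had 2 rises and 2 falls among 16, and the iron regulon 1 rise and 1 fall among 15. FLO1 had a log2 of 0.43 at a q of 1 and counts as not tested, so its response to short-term argon is not known here. The flocculation and adhesion list had 1 rise, MGA1 at 0.76, and 1 fall, FLO5 at -1.01, among 11. Ribosomal protein genes had 1 rise among 135, RPL41A, which was listed at 10. Even so, 119 were above 0, with a list median of 0.17 at percentile 100. No ribosome biogenesis gene was called among 37, and their median of -0.09 lay at percentile 2.46. It no longer passed the percentile limit without values of 10 or -10. No seripauperin among 1 tested and no alpha-specific gene among 4 was called, and 0 a-specific genes were tested. Strain markers had 2 rises among 5, OLE1 and SPT23, and their median did not stay past the limit with genes at a q of 1 included. At a q under 0.01 the calls numbered 156 in place of 398.

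The fifth comparison asks what long-term oxygen limitation changes. In the authors' deposited table, 1372 genes rose and 1052 fell between growth in a microfermenter and aerobic growth. OLE1 was 9.22-fold higher (log2 3.20, q 0.000304) and MGA2 was 4.70-fold higher (log2 2.23), while SPT23 had a log2 of 0.40 at a q of 0.143. Ergosterol synthesis rose in 25 of 26 genes, and anaerobic cell wall and sterol uptake genes in 9 of 10. Ribosomal protein genes fell in 128 of 133 with none called higher. FLO1 was 58.9-fold higher (log2 5.88). The reference group is described only as aerobic growth, so its vessel is not given and may differ as well. The heat shock, glucose-repressed and ribosome biogenesis lists were fixed to stand for growth state, and they too had many calls in ArgonLT. Effects of oxygen supply, vessel and growth state therefore cannot be told apart here.

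Beside FLO1, the largest finite rises in ArgonLT were those of the seripauperins PAU2 at 9.59 (q 0.0371) and PAU5 at 9.44, the mannoproteins TIR4 at 7.37, TIR1 at 6.85, TIR2 at 6.54 and TIR3 at 5.57, HES1 at 7.27, INO1 at 6.29 and YPL272C at 5.60. The largest falls in the authors' deposited table were those of CWP1 at -3.55, the histone gene HTA2 at -3.39, ADE17 at -3.38, GAS3 at -3.37, MTD1 at -3.34, TDA6 at -3.33, PHO3 at -3.13, FUR1 at -3.06, SEN34 at -3.01 and HO at -2.99. Of 14 tested seripauperins 11 rose and none fell, and 9 of the 14 were listed at 10, that is at 0 in the reference. Members of this family share sequence, so the values of its single genes are uncertain.

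Most genes of the lipid lists rose in ArgonLT. Ergosterol synthesis had a median of 1.24 at percentile 100 in the authors' deposited table, with ERG28 at 3.31, ERG5 at 2.56 and CYB5 at 2.17. Fatty acid synthesis had 8 rises and 3 falls among 13, with FAS2 at 2.02 and the reductase IFA38 of chain elongation at -1.23, and its median of 0.70 lay at percentile 97.0. Phospholipid and inositol synthesis rose in 10 and fell in 1 of 17, with OPI3 at 2.88 and INO2 at 2.43. Rox1 targets rose in 6 of 8, with ANB1 at 5.20, HEM13 at 2.63 and ROX1, the hypoxic repressor, at 2.24. Beta-oxidation genes rose in 13 of 16 and fell in none (median 1.80, percentile 100), with POX1 at 4.26.

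Most amino acid and sulfur genes rose in ArgonLT. Methionine and sulfur genes rose in 22 and fell in 2 of 28 in the authors' deposited table (median 1.80, percentile 100), with STR3 at 3.90 and MET1 at 3.46, and amino acid synthesis rose in 23 of 32 and fell in none, with ARG3 at 4.67 and ARG4 at 3.56. Ribosomal protein genes had a median of -1.98, with RPL9A at -2.89, and ribosome biogenesis genes fell in 19 of 37 with none called higher, NOP1 being at -1.59. Glycolysis and fermentation fell in 15 and rose in 6 of 28 (median -1.06, percentile 0), with HXK1 at 3.78, TDH1 at 3.66 and ADH1 at -2.06. Respiratory chain genes fell in 16 and rose in 4 of 32, with the NADH dehydrogenases NDE1 at -2.31 and NDE2 at 3.06. The TCA cycle fell in 7 and rose in 3 of 17, with ACO1, aconitase, at -1.80.

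Glucose-repressed genes rose in 11 of 16 and fell in none in ArgonLT, with SIP4 at 3.36 and PCK1 at 3.04. Per the authors' deposited table heat shock and stress genes rose in 12 and fell in 4 of 24, with HSP26 at 4.19 and GPH1 at 3.60. The iron regulon rose in 11 and fell in 3 of 18, with TIS11 at 4.51 and FIT2 at 3.02. Cell wall integrity genes rose in 9 and fell in 5 of 21 (median 0.49, percentile 93.9), with PIR3 at 4.12. The flocculation and adhesion list had 5 rises, among them AGA1 at 2.61 and FLO9 at 2.60, and 2 falls, MGA1 at -2.30 and TUP1, among 13. Its median of 0.27 lay at percentile 70.4, and 42.5% of all tested genes were called in ArgonLT. The unfolded protein response had 2 rises and 1 fall among 16, and the phosphate regulon 5 rises, led by PHO84 at 2.89, and 2 falls among 12. Of the a-specific genes 3 of 4 rose, STE2 at 2.32, STE6 at 1.52 and BAR1 at 0.99 (median 1.92, percentile 99.4). Of the alpha-specific genes 2 of 4 fell, MF(ALPHA)2 at -1.50 and STE3 at -0.74 (median -0.53, percentile 9.71). Both lists were fixed to stand for cells of another mating type or strain. Whether such cells were present in ArgonLT was not tested and stays open. Strain markers rose in 3 of 5, namely OLE1, MGA2 and MET17 at 1.88. With a minimum change of 2-fold the calls numbered 1486 in place of 2424, and the median of the heat shock list did not stay past percentile 97.5 with genes at a q of 1 included.

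Read side by side, 680 genes were called in 3 or more of the 5 comparisons of the authors' deposited table, 179 in 4 or more and 18 in all 5. Of the 18, 7 had the same direction throughout. The 10 of these with the largest mean absolute change were YGL039W, TDH1, RTS3, BNA1, TIP1, PLB2, OAC1, MET5, ATF1 and LEU1. TDH1, a glyceraldehyde-3-phosphate dehydrogenase, rose in all 5, by between 0.59 and 3.66, as did the cell wall mannoprotein TIP1, by between 1.18 and 2.10, and the phospholipase PLB2, by between 0.83 and 3.27. MET5, LEU1 and OAC1 fell in OLE1met250 and with both fragments and rose in ArgonST and ArgonLT. BNA1 fell in OLE1met250, at -1.87, and rose in the other 4. YGL039W, RTS3 and ATF1 fell with the SPT23 fragment and rose in the other 4. At a q under 0.01, 322 genes were called in 3 or more comparisons.

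FLO1 was called higher in the authors' deposited table in every comparison but ArgonST, where its q was 1 and it counts as not tested. The MGA2 fragment and ArgonLT shared the most genes in the same direction, 661, against 247 for independent lists, and 65 in opposite directions against 238.3. Across 5465 genes their log2 fold changes had a Pearson r of 0.46 and a Spearman rho of 0.458. INO1 and OLE1 were among the genes higher in both. MGA2 was too, but the plasmid carried it in the fragment comparison, so its rise there was set by the design. Ribosomal protein genes fell in both, in 72 of 136 and in 128 of 133 tested members. The SPT23 and MGA2 fragments shared 210 genes in the same direction, against 70.5, and 29 in opposite directions, against 68.4, with an r of 0.118 and a rho of 0.254. OLE1met250 and the MGA2 fragment shared 386 in the same direction against 191.2 and 148 in opposite directions against 187.4, with an r of 0.212 and a rho of 0.195.

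ArgonST and ArgonLT shared 229 genes in the same direction against 83.8 for independent lists, and 27 in opposite directions against 80.0, with an r of 0.346 and a rho of 0.262. Both are set against the same BY libraries in the authors' deposited table, and part of that excess may come from the shared controls, which can be neither split nor simulated without values per library. OLE1met250 and ArgonLT shared 573 in the same direction and 426 in opposite directions, against 394.2 and 388.8, with an r of 0.1. The SPT23 fragment and ArgonLT shared 273 against 144.5 in the same direction and 105 against 141.6 in opposite directions, with an r of 0.254. The SPT23 fragment and ArgonST shared 33 against 23.0 in the same direction and 58 against 22.3 in opposite directions, with an r of -0.003. OLE1met250 and the SPT23 fragment shared 198 against 112.3 in the same direction and 119 against 111.0 in opposite directions. For OLE1met250 and ArgonST these were 90 against 64.4 and 64 against 63.0. For the MGA2 fragment and ArgonST they were 77 against 42.2 and 42 against 38.2. In these pairs r was between 0.045 and 0.09. All these numbers are across genes, which are not independent replicates, and with a q under 0.01 each of the 10 counts of genes shared in the same direction changed by more than 1.5 times.

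**Figure D4:**
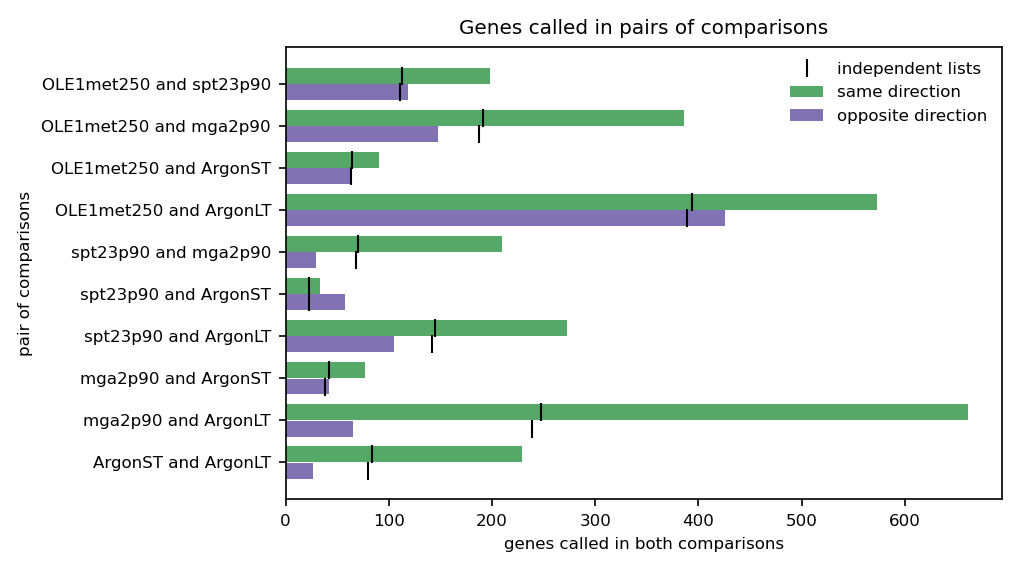
Genes called at a q under 0.05 in both comparisons of a pair (horizontal axis, number of genes), in the same or opposite direction, for all 10 pairs (vertical axis, each named by its first group), with black marks for the number that independent lists would share. The pair of the MGA2 fragment and ArgonLT had 661 genes in the same direction against 247.

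The effects of the 2 fragments were set against each other as differences of log2 fold changes in the authors' deposited table, without a test. Of 1550 genes tested with both fragments and called with either, 476 differed by 1 or more, 154 with the higher value for the SPT23 fragment and 322 for the MGA2 fragment. The target genes rose unequally, SPT23 by 2.55 with its fragment and MGA2 by 3.73 with its own. The level of a fragment and its activity therefore cannot be told apart in these counts. Apart from MGA2, the values furthest towards the MGA2 fragment were those of YGL039W (-1.39 against 3.81), HES1 (1.42 against 6.58) and YGR066C (-0.96 against 3.57). INO1 was at 1.72 against 5.61 and OLE1 at 1.11 against 2.18. Those furthest towards the SPT23 fragment were AQY1 (2.55 against -0.98), YLR049C (0.97 against -2.55) and QCR10 (1.00 against -2.07). Of these, HES1 and AQY1 were not called with the MGA2 fragment (q 0.231 and 0.230), and YGR066C and QCR10 were not called with the SPT23 fragment (q 0.123 and 0.0888). FLO1 was at 3.72 against 2.40, and TIR1 at 2.20 against -0.74.

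ArgonLT was set against ArgonST in the same way, where the shared reference cancels and the difference is the log2 ratio of both hypoxic groups in the authors' deposited table. Of 2389 genes tested in both and called in either, 1192 differed by 1 or more, 633 with the higher value in ArgonLT and 559 in ArgonST. TIR4 (7.37 against 0.99) and INO1 (6.29 against 0.10) were among those higher in ArgonLT, and OLE1 was at 3.20 against 0.72. FLO1, at 5.88 against 0.43, is not in this count, as its q in ArgonST was 1. CWP1 (-3.55 against 0.37), HTA2 (-3.39 against 0.27) and the ribosomal protein gene RPL9A (-2.89 against 0.22) were among those lower. ANB1 differed by -0.40 and HEM13 by -0.21. These differences were not tested.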

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

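No paired analysis was possible because the values are the authors' log2 fold changes and q values per comparison, with no column per library. For the same reason leaving out each replicate, a fit of all 9 groups, a recomputed adjustment of p values, expression filters, other pseudocounts, fold changes recomputed from group levels, list matching on expression and centring on well-expressed genes were planned and not run. What depth limits cannot be given, as depth is unknown. The settings that leave out values of 10 or -10, keep only genes matched to RefSeq, include genes at a q of 1 or centre on the median were chosen after seeing the data, as was a q under 0.01 for the differences of effects. With a q under 0.01 the calls numbered 342 of 695 for the SPT23 fragment, 628 of 1165 for the MGA2 fragment and 156 of 398 in ArgonST, and 322 in place of 680 genes were called in 3 or more comparisons. With a minimum change of 2-fold the calls numbered 937 in OLE1met250, 271 for the SPT23 fragment, 456 for the MGA2 fragment, 115 in ArgonST and 1486 in ArgonLT. Stricter limits pass fewer genes by construction. The other 12 counts of calls under these settings, the 4 counts of differences between effects and the 2 remaining counts of shared calls stayed within 1.5 times, as did the 2 counts of list medians past the percentile limits. Of the counts of rises alone 8, and of falls alone 9, moved by more. Of the comparisons of list medians with their alternatives, 335 kept their side of the percentile limits, 8 moved inside and 2 moved outside, and none changed sign. The cause was not tested. None of the 367 values of named genes changed direction after centring. For called genes this was fixed in advance, as the smallest called absolute log2 was 0.51 and the largest median subtracted was 0.10.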

Other observations

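The lists, tests and genes of this part were chosen after the data had been examined, except that the haploid-specific, pheromone and zinc lists and their 3 tests were written before those lists' values were seen. In the authors' deposited table, biotin genes rose with the MGA2 fragment and in ArgonLT in 5 of 5 members, with medians of 3.77 and 2.33, and with the SPT23 fragment in 4 of 5, with a median of 1.67. BIO3, of biotin synthesis, was at 5.25, 4.40 and 2.56 in these 3 comparisons. VHT1, the biotin transporter, was at 3.77 and 2.14 in the first pair and at -0.05 with a q of 0.895 with the SPT23 fragment. In OLE1met250 2 of 5 rose, and in ArgonST none of 4 tested was called.

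Thiamine genes fell in 10 of 11 members in the group labelled OLE1met250 in the authors' deposited table, with a median of -1.97 and THI4, of thiazole synthesis, at -3.48. They rose in 6 of 11 with the MGA2 fragment, with a median of 1.27 and THI4 at 3.07, in 2 of 9 with the SPT23 fragment, and in 5 of 11 in ArgonLT, where THI80 fell with a value of -1.24. In ArgonST 1 of 9 fell. Pheromone response genes rose in 9 of 14 members with the SPT23 fragment, with PRM1 at 2.08 and FUS1 at 1.43, and in 8 of 14 in ArgonLT, where CIK1 fell with a value of -1.22. With the MGA2 fragment they had 3 rises and 1 fall among 10, and in ArgonST 1 rise among 10. Zinc genes had 3 rises and 4 falls among 13 in OLE1met250, 1 rise among 12 in ArgonST, and 2 rises and 5 falls among 12 in ArgonLT. Haploid-specific genes rose in 2 of 6 with the MGA2 fragment, in 1 of 6 in ArgonST and in 2 of 6 in ArgonLT, and none was called with the SPT23 fragment.

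OLE1 was not lower in the group labelled OLE1met250, although its promoter was to be repressed there. Libraries carrying the MGA2 plasmid, which MGA2 at 4.33 brings to mind, would also carry URA3, the plasmid's marker. The log2 of URA3 was listed at -10, read here as 0 in OLE1met250, which goes against such libraries. With a q of 1, however, URA3 counts as not tested, so this rests on 1 untested value and does not exclude them. A MET3 promoter that was not repressed at collection may account for the value of OLE1, since MET3 itself, transcribed from the same kind of promoter, had a log2 of 0.36. This rests on MET3 alone, and other genes of the methionine and sulfur list fell, such as MET16 at -3.10. The title gives 250 for that group and the file headers name it as with methionine, and the treatment label gives 0 uM and the word repressed, so most of the labels point to methionine being present, and its level at collection is not given in the sources used here. The methionine and sulfur list, in which 14 of 29 members fell, does not settle the methionine level. With the SPT23 fragment 16 of 28 also fell, and 31 of 32 amino acid synthesis genes fell in OLE1met250. The members were the same only in part. MET5 and MET17 fell in both, while SUL1 and MET32, at -2.00 and -1.63 in OLE1met250, were not called with the SPT23 fragment. A loss of desaturase activity at an unchanged transcript level was not tested.

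Mating genes were lower in the group labelled OLE1met250. Diploid cells in that group are argued against by 6 haploid-specific genes that pheromone does not induce, whose median log2 was -0.147 with 1 of 6 lower. A weaker pheromone response may account for the pattern, as 9 of 13 tested pheromone response genes fell and none rose, with SST2 at -2.98 and PRM1 at -2.93. Such genes are themselves mating genes, so this count restates the pattern in part and is only weak support for a weaker pheromone response. A few a cells among alpha cells in the OLE1met0 group would give both such a response and the a-specific transcripts (STE2 at -4.19, MFA1 at -4.51 with a q of 0.104). This stays open, because pheromone also induces alpha-specific genes, all 4 of which fell, and so does a biological effect of the membrane.

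Of the iron regulon, 12 of 20 tested genes rose with the SPT23 fragment, and 8 of 18 rose and 1 fell with the MGA2 fragment. Low zinc in the cultures expressing a fragment cannot be told apart from no change in zinc, since 4 of 13 and 5 of 12 tested zinc genes rose and none fell, where at least 5 with each fragment had been required. Their medians of 0.38 and 0.51 lay at percentiles 99.4 and 99.2, while ZRT1, the high-affinity zinc transporter, was at 0.38 and 0.23 with q values of 0.340 and 0.589. An effect of the fragments and effects of doxycycline stay open, because the drug and the fragment change together in this design.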
